A study of Homo sapiens with 18 samples.

How the data were processed

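Polyadenylated RNA from LNCaP cells was sequenced in 18 libraries, 3 for each of 6 conditions, after 72 h with DMSO, 2-77 (1 µM), ACBI (0.2 µM), BD98 (2 µM), P-16 (10 µM) or ENZA (10 µM). Cells grew in medium with serum, and libraries were made from messenger RNA with a stranded kit. Per the labels, the authors used STAR, Partek and DESeq2 with genome build hg38, without version numbers. The program that assigned reads to genes, its annotation and any filter are not stated. The deposited table holds expected_counts, that is estimated counts of reads per gene and library with decimals, not scaled to depth, for 20145 genes with chromosome, start, stop and strand. The columns named SCO277 were taken as 2-77 and those named PB_16 as P-16, and 0 columns were left unused. The base before the listed stop was taken as the end of a gene, and 57.8% of 19302 genes matched by symbol and chromosome then had both ends equal to those of a RefSeq annotation of the same genome. Column totals ran from 16835093 to 36975028 counts. A count of 3, the floor used for genes at 0 in a group, equals 0.0811 to 0.178 CPM in 1 library.

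Counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with the 6 groups, which left 15422 genes and took out 4723. Library sizes were scaled by TMM factors, a robust quasi-likelihood model was fitted to all 18 libraries with 12 residual degrees of freedom, and contrasts were tested with the two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, and 0.05 was the threshold. The common biological coefficient of variation was 0.0573. The contrasts were each compound against DMSO and 2-77 against each other compound. Between replicates, the chi-square per degree of freedom of counts was 1.88 to 5.87, except for ACBI replicate 3 against replicates 1 and 2 (13.8 and 9.08). Intervals and floors cover counting error or the spread between these libraries only, since reads carry no molecular identifiers. Libraries were treated as unpaired: residuals of 12 of 45 pairs of same-number libraries from different groups were correlated above 0.1, at a median of -0.062. All 3 such pairs of 2-77 with ACBI were among the 12 (0.334, 0.405 and 0.646).

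The gene lists, the named-gene rule, the tests and most alternatives were fixed before the data were examined. The rule named, per contrast with DMSO, the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, at least 4 CPM in the higher group and all 3 treated libraries on one side of all 3 controls. It added the 4 members with the smallest p of each list that was called or had a share of at least 0.25 of its members changed, and a panel of 16 genes. Direct contrasts took 5 genes per direction. Genes with only a clone or locus name were passed over. Of the genes so named, not all are reported here.

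The 26 lists, from textbook knowledge, covered androgen-induced and androgen-repressed genes, DNA replication, mitosis, MYC targets and ribosome biogenesis, cholesterol synthesis, fatty acid synthesis, the integrated stress response, the unfolded protein response, p53 targets, interferon response, antigen presentation, NF-kB targets, BAF and PBAF subunits, BET-inhibitor-induced genes, hypoxia and glycolysis, NRF2 targets, aryl hydrocarbon receptor targets, heat shock response and metallothioneins. Markers of luminal, basal, neuroendocrine, mesenchymal and immune cells and mitochondrially encoded genes completed them. Of 493 genes on the lists, 6 stood on 2 lists, among them ALDH1A3, NQO1, SLC7A11 and SLC7A5. The 24 lists with at least 5 measured members were tested with camera in limma 3.58.1 on voom weights, with a preset correlation between genes of 0.01 and adjustment over 120 tests. Of 56 list calls, 47 held with an estimated correlation.

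Simulated data were tested. Folds of 1.25, 1.5, 2 and 4 set into 50 genes each of 15053 in the contrast of 2-77 with DMSO were recovered in 66%, 78%, 84% and 90% of cases, and 15 of 191 calls (7.9%) were of unchanged genes. The other calls were 159 of these genes and 17 of a list of 30 genes shifted by 0.3 (log2), all in the right direction, and camera called that list. Of 50 unshifted lists, 0 had an unadjusted p under 0.05, which is no guide to real lists (correlation up to 0.334). Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors or library totals in edgeR, no filter or a stricter filter, a fit of only the groups compared, a replicate block, the removal of each library in turn, and for lists an estimated correlation, the fry rotation test, library totals and a replicate block. Fits without ribosomal RNA genes, lists without ACBI replicate 3, list tests of the direct contrasts and simulations of shared calls were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.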

Results

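RNA sequencing was performed on LNCaP cells, a human prostate adenocarcinoma line, after 72 h in one of 6 conditions with 3 libraries each. The conditions were DMSO vehicle, 2-77 at 1 µM, ACBI at 0.2 µM, BD98 at 2 µM, P-16 at 10 µM and ENZA at 10 µM. ENZA is enzalutamide, an antiandrogen. The title of the series concerns selective inhibitors of the bromodomain of BRD7, a subunit of the PBAF chromatin remodelling complex, and their activity in prostate cancer. The labels state no target for 2-77, ACBI, BD98 or P-16. The 18 libraries held 16835093 to 36975028 counts over 20145 genes. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so each p measures only the spread between these libraries. The doses differed between compounds, so every contrast of compounds is also a contrast of doses.

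The first principal component of log2 counts-per-million (CPM) values held 58.4% of the variance and set the 3 ACBI libraries apart from the other 15. Components 2 and 3 held 11.4% and 9.3%. Ribosomal RNA transcripts took 8.6% of the counts in ACBI replicate 3, against 0.99% and 1.13% in ACBI replicates 1 and 2 and 0.64% to 2.09% in the libraries of the other groups. All values below are log2 fold changes with the standard error (SE), positive where the first group was higher, for groups of 3 libraries unless another measure is named. Levels are mean CPM ± SD. Where no count adjusted over the list alone is given for a gene list, it equalled the count adjusted over all 15422 genes tested. Positions are hg38 coordinates of the whole gene as deposited.

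**Figure D1:**
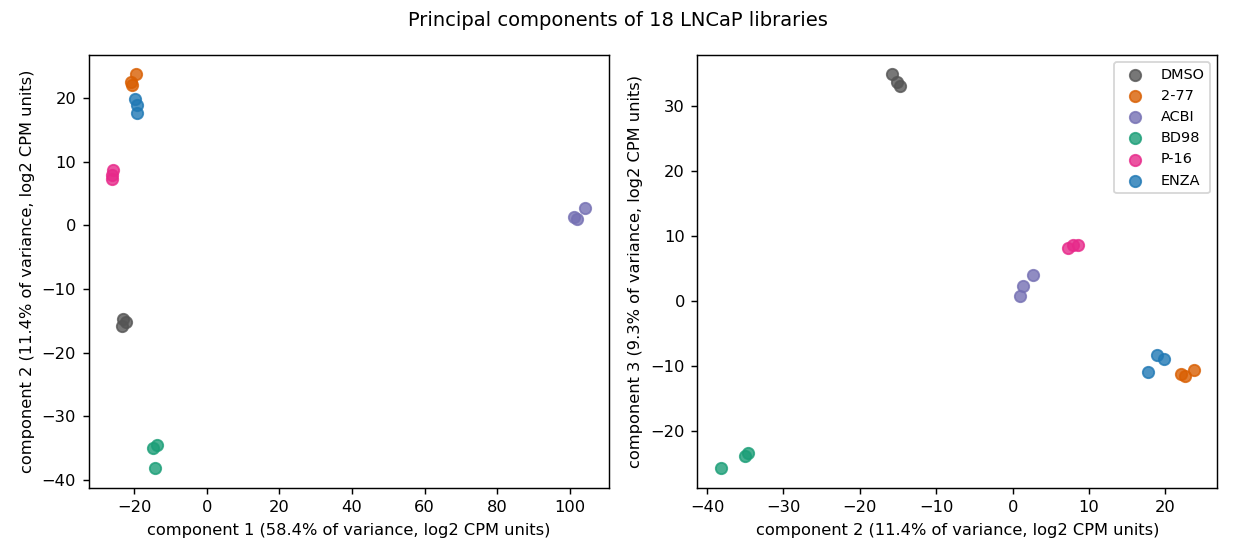
Position of each of the 18 libraries on principal components 1 and 2 (left) and 2 and 3 (right) of log2 CPM, coloured by condition, with the share of variance on each axis in percent. Component 1 (58.4%) separates the 3 ACBI libraries from the other 15 libraries.

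The contrast of 2-77 with DMSO asks which transcripts differ after 72 h with the compound at 1 µM. The classical androgen-induced genes were lower with 2-77. KLK3, which encodes prostate-specific antigen, fell 5.8-fold, from 4277 ± 46.6 CPM in DMSO to 737 ± 23.7 CPM (-2.54 ± 0.033, n = 3 per group, edgeR adjusted p = 9.35e-31). OPRK1, the kappa opioid receptor gene, rose 7.12-fold, from 2.79 ± 0.761 to 20.1 ± 1.77 CPM (2.83 ± 0.13, adjusted p = 4.26e-17). KLK3 lies on chromosome 19 from 50854915 to 50860764 and OPRK1 on chromosome 8 from 53225716 to 53251697.

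In this contrast 6280 of 15422 genes (40.7%) changed, 3169 up and 3111 down. Of these, 393 rose and 323 fell by at least 2-fold. The 8 largest falls were ADAM7 (-5.36 ± 0.26), CHRNA2 (-4.95 ± 0.19), TRPM8 (-4.56 ± 0.12), HPGD (-4.41 ± 0.19), TARP (-4.37 ± 0.11), WWTR1 (-4.27 ± 0.26), ST6GALNAC1 (-4.18 ± 0.15) and GRIN3A (-4.16 ± 0.10). TRPM8 is the cold-sensing ion channel, CHRNA2 and GRIN3A are subunits of the nicotinic acetylcholine and NMDA glutamate receptors, and HPGD degrades prostaglandins. The TRPM8 level was 1.46 ± 0.282 CPM against 34.3 ± 2.21 in DMSO. The 8 largest rises were PLD1 (3.16 ± 0.21), SCNN1B (3.16 ± 0.18), OPRK1 (2.83 ± 0.13), COL5A1 (2.78 ± 0.26), MAN1A1 (2.54 ± 0.13), FAM131B (2.28 ± 0.16), DIPK2B (2.22 ± 0.21) and KTI12 (2.15 ± 0.36). PLD1 is a phospholipase D and SCNN1B a subunit of the epithelial sodium channel. Among these 16 genes the highest adjusted p was 0.00018, for KTI12.

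Of the fixed list of androgen-induced genes, 39 of 44 measured members fell, 3 rose and 2 did not pass (3 up and 40 down adjusted over the list alone). The androgen-induced list had a median of -1.21 (list test adjusted p = 1.08e-35). Among its members with the smallest p were KLK2 (-3.64 ± 0.040), KLK3 (-2.54 ± 0.033) and TMPRSS2 (-2.56 ± 0.038). Of the androgen-repressed genes, 12 of 15 measured members rose, 2 fell and 1 did not pass. The androgen-repressed list had a median of 0.82 (list test adjusted p = 8.72e-07). UGT2B15 and UGT2B17, which glucuronidate androgens, rose (1.71 ± 0.046 and 1.08 ± 0.039), as did the kinase inhibitor gene CAMK2N1 (1.21 ± 0.043). In the mitosis list, 35 of 36 measured members fell, 0 rose and 1 did not pass; its examples were CCNB1 (-0.57 ± 0.038), MKI67 (-0.61 ± 0.042), PLK1 (-0.85 ± 0.060) and HMMR (-0.86 ± 0.061). The mitosis list had a median of -0.59 (list test adjusted p = 2.92e-24). In the DNA replication list, 20 of 35 measured members fell, 1 rose and 14 did not pass. The DNA replication list had a median of -0.19 (list test adjusted p = 6.25e-06). RRM2, a subunit of ribonucleotide reductase, fell (-0.59 ± 0.048), and so did CDT1, which licenses replication origins (-0.71 ± 0.061). In the list of MYC targets and ribosome biogenesis, 22 of 30 measured members fell, 0 rose and 8 did not pass (0 up and 23 down adjusted over the list alone), with SRM (-0.39 ± 0.041), NOLC1 (-0.30 ± 0.035), WDR74 (-0.41 ± 0.059) and DDX21 (-0.24 ± 0.040). The MYC and ribosome list had a median of -0.19 (list test adjusted p = 8.45e-07). The highest adjusted p among the genes of this paragraph was 1.58e-05.

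Genes of hypoxia and glycolysis were higher with 2-77. There, 15 of 19 measured members rose, 1 fell and 3 did not pass, with PFKFB3 (1.27 ± 0.050), PGK1 (0.54 ± 0.031), EGLN3 (1.22 ± 0.073) and PFKFB4 (1.08 ± 0.066). The hypoxia list had a median of 0.49 (list test adjusted p = 2.61e-11). PFKFB3 and PFKFB4 make the glycolytic activator fructose 2,6-bisphosphate and EGLN3 is an oxygen-sensing prolyl hydroxylase. PFKFB3 lies on chromosome 10 from 6144921 to 6254648. Genes of the integrated stress response, which the transcription factor ATF4 drives, were lower: 18 of 20 measured members fell, 0 rose and 2 did not pass. The integrated stress response list had a median of -0.54 (list test adjusted p = 2.02e-16). Examples were TRIB3 (-1.18 ± 0.039), MTHFD2 (-0.92 ± 0.041), CHAC1 (-1.39 ± 0.063) and STC2 (-0.68 ± 0.035). In the unfolded protein response, 14 of 18 measured members fell, 2 rose and 2 did not pass, with HERPUD1 (-0.57 ± 0.042), XBP1 (-0.46 ± 0.035) and ERN1 (-0.55 ± 0.044). The unfolded protein response list had a median of -0.28 (list test adjusted p = 3e-05). Heat shock genes rose: 9 of 15 measured members rose, 1 fell and 5 did not pass, with HSPA1B (0.53 ± 0.034), HSP90AA1 (0.47 ± 0.035) and HSPH1 (0.41 ± 0.039). The heat shock list had a median of 0.16 (list test adjusted p = 0.000154). Of genes that BET bromodomain inhibitors induce in other cells, 7 of 11 measured members rose, 0 fell and 4 did not pass (9 up and 0 down adjusted over the list alone), with H1-2 (0.45 ± 0.048), HEXIM1 (0.39 ± 0.042) and SERPINI1 (0.64 ± 0.11). The BET-inhibitor-induced list had a median of 0.33 (list test adjusted p = 0.00179). HEXIM1 inhibits the transcription elongation factor P-TEFb. The highest adjusted p among these genes was 3.21e-05.

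Lists that the test did not call for 2-77 were cholesterol synthesis (3 up and 8 down of 24, 3 and 9 adjusted over the list alone, adjusted p = 0.0746), fatty acid synthesis (7 up and 5 down of 16, 7 and 6 adjusted over the list alone, adjusted p = 0.575), p53 targets (7 up and 5 down of 24, 8 and 5 adjusted over the list alone, adjusted p = 0.366), interferon response (5 up and 2 down of 32, adjusted p = 0.439) and antigen presentation (6 up and 2 down of 14, 7 and 2 adjusted over the list alone, adjusted p = 0.0598). The remaining ones were NF-kB targets (0 up and 4 down of 8, 0 and 5 adjusted over the list alone, adjusted p = 0.0764), NRF2 targets (3 up and 4 down of 15, adjusted p = 0.751), aryl hydrocarbon receptor targets (2 up and 3 down of 8, adjusted p = 0.516) and metallothioneins (0 up and 2 down of 5, adjusted p = 0.0815). Members of the fatty acid list still changed singly. The fatty acid elongases ELOVL7 and ELOVL5 fell (-2.36 ± 0.080 and -1.66 ± 0.053), with a highest adjusted p of 2.75e-18. For fatty acid synthesis the median was 0.02 and the mean -0.25, with the test pointing down.

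The contrast of ACBI with DMSO covers the compound with the most changed genes of the 5. Proliferation genes were far lower with ACBI. The proliferation marker MKI67 fell 23.8-fold, from 229.9 ± 5.82 to 9.65 ± 0.697 CPM (-4.57 ± 0.055, n = 3 per group, adjusted p = 8.65e-32), and the growth regulator MYC fell 9.92-fold (-3.31 ± 0.047, adjusted p = 2.52e-30). HES6, which encodes a basic helix-loop-helix regulator, rose 31.2-fold, from 184 ± 3.56 to 5733 ± 172 CPM (4.96 ± 0.056, adjusted p = 2.94e-29). Androgen-induced genes went both ways: KLK3 fell 6.54-fold (-2.71 ± 0.033) while FKBP5, a co-chaperone of steroid receptors, rose 4.19-fold (2.07 ± 0.042). MKI67 lies on chromosome 10 from 128096661 to 128126423, HES6 on chromosome 2 from 238238267 to 238240038 and MYC on chromosome 8 from 127735434 to 127742951.

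Of 15422 genes, 11097 (72.0%) changed, 5460 up and 5637 down, with 1188 up and 2016 down by at least 2-fold. Under TMM scaling (median -0.008 over all genes) rises and falls were relative, not per cell. Without ACBI replicate 3 the count was 10945 (5473 up and 5472 down), and no list call changed. The largest rises were SH3D21 (5.27 ± 0.066), HES6 (4.96 ± 0.056), GALNT12 (4.87 ± 0.28), LAT2 (4.85 ± 0.13), TLL2 (4.76 ± 0.15), CHRM4 (4.68 ± 0.30), ENTPD8 (4.57 ± 0.31) and GLI1 (4.32 ± 0.42). CHRM4 is a muscarinic acetylcholine receptor and GLI1 a transcription factor of hedgehog signalling. Among the largest falls, HRNR had 0 counts in the 3 ACBI libraries against 312 in DMSO, at least 128-fold lower when set against 3 counts over the group. TM4SF1 had 3 counts over the 3 ACBI libraries against 1749, a ratio of 715 (95% counting interval 244 to 3.47e+03). MRGPRE had 1 against 279, a ratio of 342 (60.9 to 1.36e+04). Other large falls were PCAT1 (-7.85 ± 0.15), DIO3 (-7.58 ± 0.13), RYR2 (-7.42 ± 0.18) and OR51E1 (-6.72 ± 0.21). DIO3 inactivates thyroid hormone. The highest adjusted p among the genes with a fitted value here was 6.98e-09.

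With ACBI, 35 of 36 measured members fell, 0 rose and 1 did not pass in the mitosis list. The mitosis list had a median of -4.06 (list test adjusted p = 8.3e-21). The examples were TOP2A (-5.10 ± 0.065), NUSAP1 (-4.56 ± 0.063) and BIRC5 (-4.10 ± 0.068). In DNA replication, 35 of 35 measured members fell, 0 rose and 0 did not pass, with RRM2 (-5.09 ± 0.070), MCM4 (-2.45 ± 0.045), TYMS (-2.93 ± 0.058) and MCM7 (-2.04 ± 0.042). The DNA replication list had a median of -2.45 (list test adjusted p = 5.76e-19). MCM4 and MCM7 are subunits of the replicative helicase. In MYC targets and ribosome biogenesis, 30 of 30 measured members fell, 0 rose and 0 did not pass, with ODC1 (-1.64 ± 0.037), GNL3 (-1.43 ± 0.037), MYBBP1A (-1.51 ± 0.041) and DKC1 (-1.51 ± 0.041). The MYC and ribosome list had a median of -1.13 (list test adjusted p = 6.47e-15). Stress genes were lower as well. In the integrated stress response, 19 of 20 measured members fell, 0 rose and 1 did not pass, with STC2 (-3.22 ± 0.040), TRIB3 (-2.77 ± 0.042), DDIT4 (-1.99 ± 0.035) and PHGDH (-2.06 ± 0.037), and in the unfolded protein response, 14 of 18 measured members fell, 1 rose and 3 did not pass, with XBP1 (-1.43 ± 0.037), HSP90B1 (-1.07 ± 0.038) and MANF (-1.01 ± 0.045). The integrated stress response list had a median of -1.74 (list test adjusted p = 1.41e-13). The unfolded protein response list had a median of -0.48 (list test adjusted p = 7.03e-05). Without ACBI replicate 3 the members down were 35 in mitosis, 35 in DNA replication, 30 in MYC targets and 19 in the integrated stress response.

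Of the androgen-induced genes, 22 of 44 measured members rose, 18 fell and 4 did not pass (22 up and 19 down adjusted over the list alone). The androgen-induced list had a median of 0.11 (list test adjusted p = 0.572). Their mean was -0.20, opposite in sign to the median, and the test pointed up. KLK2 (-4.17 ± 0.042) and ACP3, the gene of prostatic acid phosphatase (-4.83 ± 0.062), fell, and NCAPD3, a condensin subunit, rose (2.69 ± 0.039). Of the androgen-repressed genes, 9 of 15 measured members fell, 4 rose and 2 did not pass, with CAMK2N1 (-3.59 ± 0.052), UGT2B17 (-2.88 ± 0.045), UGT2B15 (-1.92 ± 0.053) and BCHE (-2.47 ± 0.064). The androgen-repressed list had a median of -0.75 (list test adjusted p = 0.0469, and adjusted p = 0.128 with an estimated correlation). Without ACBI replicate 3 the counts were 22 up and 18 down of the androgen-induced and 4 up and 9 down of the androgen-repressed genes. In hypoxia and glycolysis, 13 of 19 measured members fell, 4 rose and 2 did not pass, with VEGFA (-1.75 ± 0.041), LDHA (-1.02 ± 0.032), HK2 (-1.35 ± 0.043) and PGK1 (-0.85 ± 0.032). The hypoxia list had a median of -0.69 (list test adjusted p = 0.00188). CA9 in that list had 0 counts with ACBI and 10 in DMSO; with CA9 put at 3 counts over the group the median was also -0.69. NRF2 targets were lower: 12 of 15 measured members fell, 2 rose and 1 did not pass, with FTH1 (-0.96 ± 0.036), TALDO1 (-0.71 ± 0.043), PGD (-0.59 ± 0.039) and TXN (-0.62 ± 0.055). The NRF2 list had a median of -0.31 (list test adjusted p = 0.0199).

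Cholesterol synthesis genes were higher with ACBI: 18 of 24 measured members rose, 3 fell and 3 did not pass, with INSIG1 (1.28 ± 0.044) and LSS (1.26 ± 0.050). The cholesterol synthesis list had a median of 0.45 (list test adjusted p = 7.67e-05). Of BET-inhibitor-induced genes, 10 of 11 measured members rose, 1 fell and 0 did not pass, with H2BC21 (1.78 ± 0.036), H1-2 (1.68 ± 0.047), HEXIM1 (1.36 ± 0.042) and H2BC4 (2.06 ± 0.076). The BET-inhibitor-induced list had a median of 1.36 (list test adjusted p = 2.45e-05). Without ACBI replicate 3 the members up were 18 and 10. No call was made for fatty acid synthesis (5 up and 10 down of 16, adjusted p = 0.41), p53 targets (7 up and 15 down of 24, 8 and 15 adjusted over the list alone, adjusted p = 0.289), interferon response (14 up and 14 down of 32, adjusted p = 0.593) or antigen presentation (4 up and 7 down of 14, adjusted p = 0.711). Nor was one made for NF-kB targets (4 up and 4 down of 8, adjusted p = 0.739), aryl hydrocarbon receptor targets (4 up and 2 down of 8, adjusted p = 0.636), heat shock response (4 up and 8 down of 15, adjusted p = 0.281) or metallothioneins (2 up and 2 down of 5, adjusted p = 0.847). Single members of uncalled lists moved far, among them the interferon-stimulated ubiquitin ligase genes HERC5 (3.07 ± 0.10) and HERC6 (2.36 ± 0.078) and the p53 target CDKN1A, a cell cycle inhibitor (-1.41 ± 0.047). Median, mean and test differed in sign for interferon response (median -0.06, mean -0.32, test up), NF-kB targets (0.02, -0.36, down) and aryl hydrocarbon receptor targets (-0.03, -0.40, up).

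The contrast of BD98 with DMSO gives the genes that differ after BD98 at 2 µM. Integrated stress response genes were lower. CHAC1, which degrades glutathione, fell 14.6-fold, from 74.5 ± 1.33 to 5.13 ± 0.217 CPM (-3.87 ± 0.081, n = 3 per group, adjusted p = 1.73e-25), and CD55, which shields cells from complement, fell 38.7-fold (-5.27 ± 0.25, adjusted p = 1.01e-16). PLA2G2A, a secreted phospholipase A2, rose 5.92-fold, from 5.92 ± 0.37 to 35.1 ± 1.41 CPM (2.56 ± 0.098, adjusted p = 4.37e-19). KLK3 fell 1.67-fold (-0.74 ± 0.031, adjusted p = 5.69e-18). CHAC1 lies on chromosome 15 from 40953471 to 40956512 and CD55 on chromosome 1 from 207321678 to 207360966.

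With BD98, 7559 genes (49.0%) changed, 3783 up and 3776 down, and 235 rose and 598 fell by at least 2-fold. Scaled to library totals alone, 7509 changed, 4640 up and 2869 down, so that 61.8% of the changed genes rose instead of 50%. The largest rises were KTI12 (2.61 ± 0.35), PLA2G2A (2.56 ± 0.098), TNC (2.44 ± 0.22), CD24 (2.29 ± 0.10), MID1 (2.18 ± 0.12), UGT2B10 (2.00 ± 0.14), S1PR3 (1.98 ± 0.080) and UGT2B11 (1.96 ± 0.069). TNC is tenascin C and S1PR3 a sphingosine 1-phosphate receptor. Among the largest falls were TRIM49D1 (-5.29 ± 0.17), CD55 (-5.27 ± 0.25), S100P (-4.78 ± 0.15), CHAC1 (-3.87 ± 0.081), LRATD1 (-3.22 ± 0.22), CAPN5 (-3.14 ± 0.098) and DIO3 (-2.84 ± 0.072). TRIM49D1 and the UGT2B genes have close paralogs, and KTI12 and TARP lie within or beside other genes, so reads of these genes are less surely assigned. None of the rises and falls listed had an adjusted p above 1.77e-05.

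In the integrated stress response, 20 of 20 measured members fell, 0 rose and 0 did not pass. The integrated stress response list had a median of -1.81 (list test adjusted p = 3.29e-29). Its examples were TRIB3 (-2.36 ± 0.041), STC2 (-1.92 ± 0.037), PSAT1 (-2.17 ± 0.042) and ASNS (-1.89 ± 0.037). In the unfolded protein response, 13 of 18 measured members fell, 1 rose and 4 did not pass, with ERN1 (-1.13 ± 0.046), XBP1 (-0.81 ± 0.036), HERPUD1 (-0.90 ± 0.043) and SEL1L (-0.60 ± 0.040). The unfolded protein response list had a median of -0.22 (list test adjusted p = 7.62e-06). NRF2 targets were lower: 10 of 15 measured members fell, 1 rose and 4 did not pass (1 up and 11 down adjusted over the list alone). The NRF2 list had a median of -0.20 (list test adjusted p = 0.00364). Among them, SLC7A11, the cystine transporter that also stands on the integrated stress response list, fell (-2.53 ± 0.11), NQO1 fell (-0.56 ± 0.054) and the ferritin light chain gene FTL rose (0.35 ± 0.041). Of the androgen-induced genes, 38 of 44 measured members fell, 2 rose and 4 did not pass (3 up and 38 down adjusted over the list alone), with ACP3 (-2.78 ± 0.051), ADAMTS1 (-1.34 ± 0.033), PMEPA1 (-1.31 ± 0.035) and TSC22D3 (-1.84 ± 0.050). The androgen-induced list had a median of -0.83 (list test adjusted p = 1.82e-22). With ENZA, ACP3 and ADAMTS1 lay above DMSO, PMEPA1 and TSC22D3 below. Of the androgen-repressed genes, 9 of 15 measured members rose, 3 fell and 3 did not pass, with UGT2B17 (1.91 ± 0.039), UGT2B15 (1.88 ± 0.046) and ACKR3 (1.04 ± 0.050). The androgen-repressed list had a median of 0.90 (list test adjusted p = 0.000567). The genes named here had an adjusted p of at most 3.9e-08.

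Replication and mitosis genes parted with BD98. In DNA replication, 22 of 35 measured members rose, 3 fell and 10 did not pass (23 up and 3 down adjusted over the list alone), with PCNA (0.42 ± 0.046), MCM4 (0.34 ± 0.040), FEN1 (0.44 ± 0.053) and MCM3 (0.31 ± 0.039), whereas in mitosis, 23 of 36 measured members fell, 0 rose and 13 did not pass (0 up and 25 down adjusted over the list alone), with CENPE (-0.95 ± 0.076), PLK1 (-0.47 ± 0.059), ECT2 (-0.57 ± 0.071) and CENPF (-0.42 ± 0.057). The DNA replication list had a median of 0.21 (list test adjusted p = 2.45e-05). The mitosis list had a median of -0.20 (list test adjusted p = 7.54e-06). In MYC targets and ribosome biogenesis, 23 of 30 measured members fell, 1 rose and 6 did not pass, with GNL3 (-0.60 ± 0.036), ODC1 (-0.45 ± 0.036), SRM (-0.47 ± 0.041) and NPM1 (-0.51 ± 0.049). The MYC and ribosome list had a median of -0.25 (list test adjusted p = 5.65e-07). Interferon response genes rose: 22 of 32 measured members rose, 3 fell and 7 did not pass, with PARP9 (0.67 ± 0.056), STAT2 (0.62 ± 0.057), OAS3 (0.61 ± 0.057) and ISG15 (0.61 ± 0.069). The interferon list had a median of 0.46 (list test adjusted p = 5.38e-05). In antigen presentation, 9 of 14 measured members rose, 2 fell and 3 did not pass, with TAPBP (0.71 ± 0.046) and TAP1 (0.45 ± 0.054), which load peptides on class I molecules. The antigen presentation list had a median of 0.36 (list test adjusted p = 0.0157). Of BET-inhibitor-induced genes, 10 of 11 measured members rose, 0 fell and 1 did not pass, with H2BC12 (0.70 ± 0.038), HEXIM1 (0.44 ± 0.043) and SERPINI1 (0.99 ± 0.11). The BET-inhibitor-induced list had a median of 0.44 (list test adjusted p = 6.88e-05). In fatty acid synthesis, 9 of 16 measured members fell, 4 rose and 3 did not pass, with ELOVL7 (-2.35 ± 0.082), SCD (-0.70 ± 0.032), ACSL3 (-0.92 ± 0.050) and ME1 (-0.79 ± 0.049). The fatty acid synthesis list had a median of -0.20 (list test adjusted p = 0.00441).

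Further calls with BD98 did not hold with an estimated correlation. In hypoxia and glycolysis, 9 of 19 measured members fell, 5 rose and 5 did not pass. The hypoxia list had a median of -0.09 (list test adjusted p = 0.0461, and adjusted p = 0.0664 with an estimated correlation). The mean of that list was 0.003, opposite in sign to its median, and VEGFA and HK2 fell (-0.89 ± 0.040 and -0.76 ± 0.042). Of the metallothioneins, 3 of 5 measured members fell, 0 rose and 2 did not pass, with MT1X at -0.96 ± 0.12. The metallothionein list had a median of -0.62 (list test adjusted p = 0.0282, and adjusted p = 0.217 with an estimated correlation). The list test made no call for cholesterol synthesis (2 up and 10 down of 24, adjusted p = 0.103), p53 targets (7 up and 10 down of 24, 8 and 10 adjusted over the list alone, adjusted p = 0.649), NF-kB targets (1 up and 3 down of 8, 2 and 3 adjusted over the list alone, adjusted p = 0.597), aryl hydrocarbon receptor targets (1 up and 3 down of 8, adjusted p = 0.0857) or heat shock response (7 up and 3 down of 15, 7 and 4 adjusted over the list alone, adjusted p = 0.254). GDF15, a stress-induced cytokine on the p53 list, fell (-1.10 ± 0.046) and BTG2, an antiproliferative gene of that list, rose (0.82 ± 0.045).

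The contrast of P-16 with DMSO concerns the compound named PB16 in the treatment protocol, at 10 µM. CYP1A1, a xenobiotic-metabolizing cytochrome that the aryl hydrocarbon receptor induces, rose 16.7-fold, from 0.637 ± 0.25 to 10.98 ± 0.618 CPM (4.06 ± 0.22, n = 3 per group, adjusted p = 8.25e-15). KLK3 fell 1.78-fold, to 2399 ± 15.3 CPM (-0.83 ± 0.031, adjusted p = 1.62e-18), and HPGD fell 11.7-fold (-3.55 ± 0.18, adjusted p = 2.47e-15). The glycolytic genes PFKFB3 and LDHA rose (0.85 ± 0.051 and 0.51 ± 0.031). CYP1A1 lies on chromosome 15 from 74719542 to 74725528 and HPGD on chromosome 4 from 174490175 to 174522898.

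P-16 changed 3699 genes (24.0%), 1914 up and 1785 down, and 152 of them rose and 146 fell by at least 2-fold. The largest rises were CYP1A1 (4.06 ± 0.22), SCNN1B (2.42 ± 0.19), FOXN4 (2.28 ± 0.25), OPRK1 (2.22 ± 0.14), STC1 (2.00 ± 0.10), WNT5A (1.66 ± 0.12), KTI12 (1.65 ± 0.38) and PLA2G4D (1.62 ± 0.14), where WNT5A is a secreted signalling protein and STC1 a secreted glycoprotein hormone. The largest falls were HPGD (-3.55 ± 0.18), ADAM7 (-3.40 ± 0.22), CHRNA2 (-2.92 ± 0.15), F5 (-2.53 ± 0.15), TRIM49D1 (-2.43 ± 0.13), UGT2B28 (-2.32 ± 0.26), WWTR1 (-2.12 ± 0.21) and ZNF812P (-2.09 ± 0.25), where F5 is coagulation factor V. ZNF812P is annotated as a pseudogene by its symbol, so its reads are less surely assigned. For all of these genes the adjusted p was at most 0.00503.

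Of the androgen-induced genes, 36 of 44 measured members fell, 2 rose and 6 did not pass (2 up and 37 down adjusted over the list alone), with PMEPA1 (-2.04 ± 0.037), CENPN (-1.70 ± 0.038) and KLK2 (-1.43 ± 0.036). The androgen-induced list had a median of -0.87 (list test adjusted p = 1.55e-47). Of the androgen-repressed genes, 10 of 15 measured members rose, 2 fell and 3 did not pass (11 up and 2 down adjusted over the list alone). The androgen-repressed list had a median of 0.65 (list test adjusted p = 1.2e-07). UGT2B17, CAMK2N1 and UGT2B15 rose (1.14 ± 0.039, 1.27 ± 0.044 and 0.86 ± 0.046) and UGT2B11 fell (-1.64 ± 0.089). In mitosis, 34 of 36 measured members fell, 0 rose and 2 did not pass, with TOP2A (-0.45 ± 0.046), NUSAP1 (-0.41 ± 0.045), HMMR (-0.56 ± 0.061) and CCNB1 (-0.34 ± 0.038). The mitosis list had a median of -0.39 (list test adjusted p = 5.2e-24). In the DNA replication list, 8 of 35 measured members fell, 0 rose and 27 did not pass, with RRM2 (-0.35 ± 0.048). The DNA replication list had a median of -0.08 (list test adjusted p = 0.00821, and adjusted p = 0.0508 with an estimated correlation). In MYC targets and ribosome biogenesis, 7 of 30 measured members fell, 0 rose and 23 did not pass, with DDX21 (-0.19 ± 0.040) and NPM1 (-0.19 ± 0.049). The MYC and ribosome list had a median of -0.06 (list test adjusted p = 0.014, and adjusted p = 0.104 with an estimated correlation). In the integrated stress response, 11 of 20 measured members fell, 3 rose and 6 did not pass (3 up and 13 down adjusted over the list alone), with TRIB3 and MTHFD2 down (-0.53 ± 0.038 and -0.48 ± 0.041) and NUPR1 up (0.34 ± 0.037). The integrated stress response list had a median of -0.15 (list test adjusted p = 0.000576, and adjusted p = 0.0513 with an estimated correlation). Adjusted p of the genes named here was at most 0.00511.

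Hypoxia and glycolysis genes rose with P-16: 18 of 19 measured members rose, 0 fell and 1 did not pass, with PFKFB4 (1.24 ± 0.066), PFKFB3 (0.85 ± 0.051), LDHA (0.51 ± 0.031) and PGK1 (0.51 ± 0.031). The hypoxia list had a median of 0.46 (list test adjusted p = 1.54e-22). Of the NRF2 targets, 9 of 15 measured members rose, 0 fell and 6 did not pass (9 up and 1 down adjusted over the list alone), with NQO1 (0.74 ± 0.052), FTH1 (0.41 ± 0.036) and TXNRD1 (0.21 ± 0.032), genes of quinone detoxification, iron storage and thioredoxin reduction. The NRF2 list had a median of 0.14 (list test adjusted p = 3.96e-05). Heat shock genes were higher: 10 of 15 measured members rose, 0 fell and 5 did not pass, with HSPH1 (0.46 ± 0.040), HSPA1B (0.33 ± 0.034), HSP90AA1 (0.33 ± 0.035) and DNAJB1 (0.28 ± 0.038). The heat shock list had a median of 0.22 (list test adjusted p = 6.71e-08). The aryl hydrocarbon receptor list, which includes CYP1A1 and NQO1, was not called (3 up and 1 down of 8, adjusted p = 0.152), and its member ALDH1A3, which also stands on the androgen-induced list, fell (-0.84 ± 0.041). Not called either were cholesterol synthesis (3 up and 3 down of 24, 4 and 5 adjusted over the list alone, adjusted p = 0.6), fatty acid synthesis (8 up and 4 down of 16, 9 and 4 adjusted over the list alone, adjusted p = 0.254), unfolded protein response (2 up and 7 down of 18, adjusted p = 0.453) and p53 targets (6 up and 3 down of 24, 7 and 3 adjusted over the list alone, adjusted p = 0.312). The same held for interferon response (1 up and 2 down of 32, adjusted p = 0.686), antigen presentation (6 up and 2 down of 14, adjusted p = 0.0504), NF-kB targets (1 up and 3 down of 8, 1 and 4 adjusted over the list alone, adjusted p = 0.118), BET-inhibitor-induced (2 up and 1 down of 11, adjusted p = 0.562) and metallothioneins (1 up and 0 down of 5, 2 and 0 adjusted over the list alone, adjusted p = 0.195). For fatty acid synthesis the median was 0.15 and the mean -0.08 with the test up, and for BET-inhibitor-induced genes they were -0.005 and 0.071 with the test up.

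The contrast of ENZA with DMSO shows the response of these cells to an antiandrogen. KLK3 fell 4.45-fold, to 961 ± 1.61 CPM (-2.15 ± 0.033, n = 3 per group, adjusted p = 6.27e-29). DAB1, an adaptor of reelin signalling, rose 14.7-fold, from 0.288 ± 0.164 to 4.29 ± 0.711 CPM (3.88 ± 0.31, adjusted p = 2.72e-11). DAB1 lies on chromosome 1 from 56994778 to 58546726.

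ENZA changed 5595 genes (36.3%), 2811 up and 2784 down, with 279 up and 313 down by at least 2-fold. The largest rises were DAB1 (3.88 ± 0.31), PLD1 (3.62 ± 0.20), OPRK1 (3.50 ± 0.12), DIPK2B (2.41 ± 0.21), MID1 (2.38 ± 0.12), VWA2 (2.25 ± 0.10), PLA2G2A (2.24 ± 0.099) and KTI12 (2.22 ± 0.36). The largest falls were TRPM8 (-4.71 ± 0.12), HPGD (-4.71 ± 0.20), ST6GALNAC1 (-4.66 ± 0.16), TRIM49D1 (-4.35 ± 0.15), CHRNA2 (-4.34 ± 0.17), PSLNR (-4.25 ± 0.30), ADAM7 (-4.15 ± 0.23) and TARP (-3.43 ± 0.10). No gene named in this paragraph had an adjusted p above 0.000148. Of the androgen-induced genes, 39 of 44 measured members fell, 2 rose and 3 did not pass, with KLK2 (-3.23 ± 0.039) and PMEPA1 (-2.28 ± 0.037) beside KLK3. The androgen-induced list had a median of -1.09 (list test adjusted p = 1.22e-38). Of the androgen-repressed genes, 12 of 15 measured members rose, 2 fell and 1 did not pass, with UGT2B15 (2.18 ± 0.046), UGT2B17 (1.52 ± 0.039), CAMK2N1 (1.45 ± 0.044) and OPRK1 (3.50 ± 0.12). The androgen-repressed list had a median of 1.05 (list test adjusted p = 1.65e-09).

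Mitosis genes were lower with ENZA: 35 of 36 measured members fell, 0 rose and 1 did not pass (0 up and 36 down adjusted over the list alone), with PLK1 (-0.97 ± 0.060), CCNB1 (-0.54 ± 0.038), MKI67 (-0.59 ± 0.042) and TOP2A (-0.64 ± 0.046). The mitosis list had a median of -0.60 (list test adjusted p = 6.22e-27). In DNA replication, 28 of 35 measured members fell, 0 rose and 7 did not pass, with RRM2 (-0.67 ± 0.048), CDT1 (-0.77 ± 0.061) and TYMS (-0.52 ± 0.048). The DNA replication list had a median of -0.28 (list test adjusted p = 2.17e-09). In MYC targets and ribosome biogenesis, 25 of 30 measured members fell, 0 rose and 5 did not pass (0 up and 28 down adjusted over the list alone), with SRM (-0.42 ± 0.041), NOLC1 (-0.28 ± 0.035) and ODC1 (-0.26 ± 0.036). The MYC and ribosome list had a median of -0.18 (list test adjusted p = 1.55e-08). In the integrated stress response, 19 of 20 measured members fell, 0 rose and 1 did not pass, with TRIB3 (-1.42 ± 0.039), STC2 (-0.86 ± 0.035), MTHFD2 (-0.91 ± 0.041) and CHAC1 (-1.37 ± 0.063), and in the unfolded protein response, 11 of 18 measured members fell, 2 rose and 5 did not pass. The integrated stress response list had a median of -0.63 (list test adjusted p = 3.67e-21). The unfolded protein response list had a median of -0.22 (list test adjusted p = 0.000498). In that list ERN1 and XBP1 fell (-0.68 ± 0.045 and -0.43 ± 0.035) and the chaperone gene CALR rose (0.30 ± 0.034). In cholesterol synthesis, 13 of 24 measured members fell, 2 rose and 9 did not pass, with TM7SF2 up (0.51 ± 0.049). The cholesterol synthesis list had a median of -0.16 (list test adjusted p = 0.0131). In fatty acid synthesis, 9 of 16 measured members fell, 2 rose and 5 did not pass, with ELOVL7 (-2.41 ± 0.081), ELOVL5 (-1.49 ± 0.053) and ACSL3 (-0.87 ± 0.050). The fatty acid synthesis list had a median of -0.14 (list test adjusted p = 0.00988). In the heat shock response, 9 of 15 measured members rose, 0 fell and 6 did not pass, with HSP90AA1 (0.44 ± 0.035), HSPA1B (0.28 ± 0.034) and DNAJA1 (0.34 ± 0.042). The heat shock list had a median of 0.18 (list test adjusted p = 0.000627). The genes named here had an adjusted p of at most 1.15e-06.

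Hypoxia and glycolysis genes showed no common direction with ENZA: 8 of 19 measured members rose, 7 fell and 4 did not pass. The hypoxia list had a median of -0.03 (list test adjusted p = 0.994). The mean of the list was 0.11, opposite in sign to its median. EGLN3 rose (0.77 ± 0.075) and HK2, VEGFA and PGK1 fell (-0.55 ± 0.042, -0.36 ± 0.039 and -0.19 ± 0.031). ENZA gave no call for p53 targets (3 up and 6 down of 24, adjusted p = 0.705), interferon response (5 up and 4 down of 32, adjusted p = 0.255), antigen presentation (7 up and 3 down of 14, adjusted p = 0.145) or NF-kB targets (0 up and 3 down of 8, adjusted p = 0.0702). It gave none for BET-inhibitor-induced (5 up and 1 down of 11, 6 and 1 adjusted over the list alone, adjusted p = 0.114), NRF2 targets (3 up and 4 down of 15, adjusted p = 0.976), aryl hydrocarbon receptor targets (1 up and 3 down of 8, adjusted p = 0.457) or metallothioneins (0 up and 2 down of 5, 0 and 4 adjusted over the list alone, adjusted p = 0.0944).

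**Figure D2:**
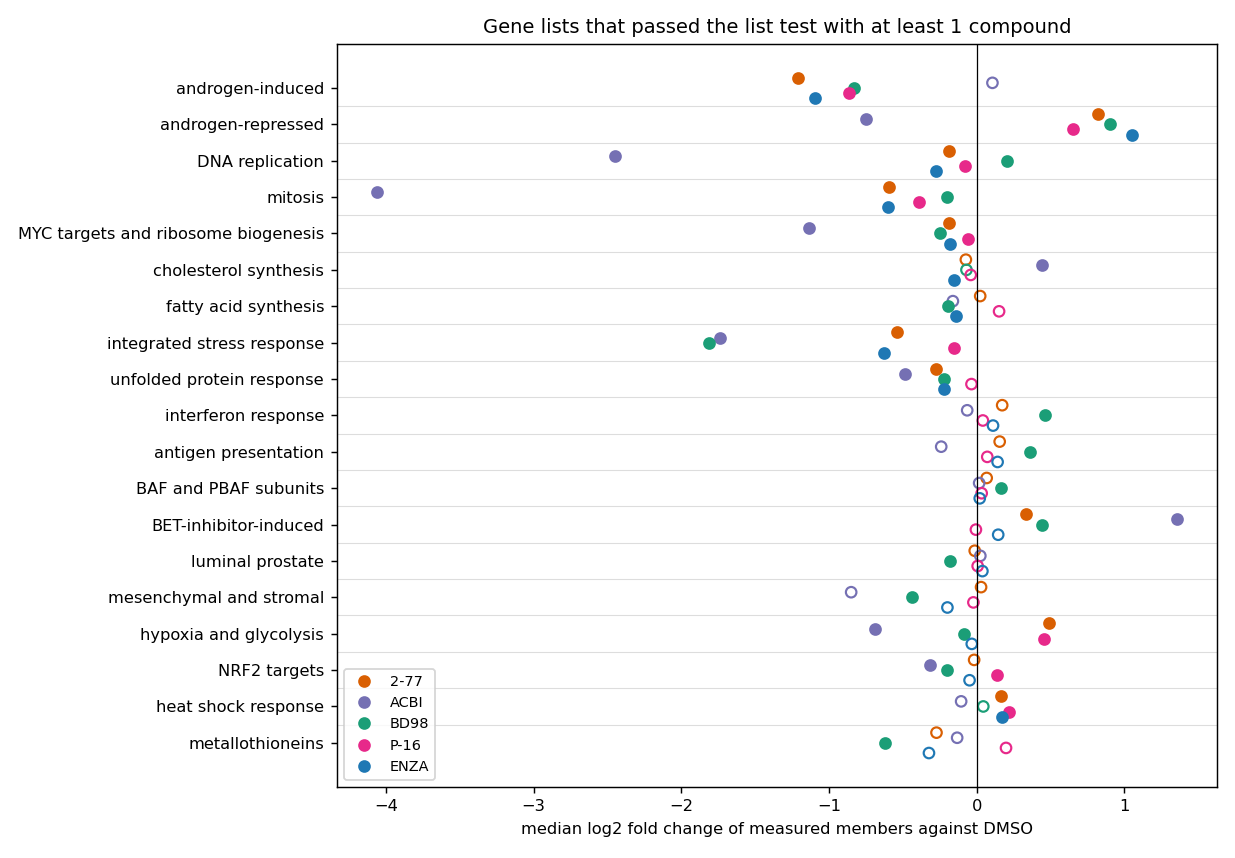
Median log2 fold change against DMSO of each fixed gene list with each of the 5 compounds, filled where the list test passed an adjusted p of 0.05 and open where it did not. Mitosis genes lie between -0.20 with BD98 and -4.06 with ACBI, and hypoxia genes at 0.49 with 2-77, 0.46 with P-16 and -0.03 with ENZA.

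Across the compounds, BRD7 transcripts passed the test with none: the values were 0.11 ± 0.061 with 2-77, 0.02 ± 0.062 with ACBI, 0.13 ± 0.062 with BD98, -0.09 ± 0.063 with P-16 and 0.02 ± 0.062 with ENZA, with a smallest adjusted p of 0.0731, for BD98 (edgeR), and BRD7 lies on chromosome 16 from 50315957 to 50368988. Its value in DMSO was 57.3 ± 2.91 CPM. BRD9, a subunit of another BAF complex, rose with 2-77 (0.29 ± 0.057) and BD98 (0.28 ± 0.058) and did not pass with the other 3 compounds (adjusted p = 0.334, 0.181 and 0.0705 for ACBI, P-16 and ENZA). PBRM1, the PBAF bromodomain subunit, fell with ACBI (-0.50 ± 0.041), BD98 (-0.37 ± 0.041) and ENZA (-0.16 ± 0.041). With 2-77 its fall (-0.15 ± 0.041, adjusted p = 0.00469) did not pass without DMSO replicate 2 (-0.11), and with P-16 its fall (-0.13 ± 0.041, adjusted p = 0.0191) did not pass without DMSO replicate 2 (-0.09), P-16 replicate 2 (-0.12) or P-16 replicate 3 (-0.12). The ATPase gene SMARCA4 fell with ACBI (-0.17 ± 0.038) and rose with 2-77 (0.13 ± 0.037) and BD98 (0.28 ± 0.037), and did not pass with P-16 (adjusted p = 0.146) or ENZA (adjusted p = 0.203). SMARCD3, a further subunit, rose with 2-77 (1.13 ± 0.073), BD98 (0.73 ± 0.075), P-16 (0.66 ± 0.076) and ENZA (0.92 ± 0.074) and fell with ACBI (-0.19 ± 0.080, adjusted p = 0.0323). The list of BAF and PBAF subunits gave 2-77 (7 up and 3 down of 27, adjusted p = 0.333), ACBI (9 up and 8 down of 27, adjusted p = 0.574), BD98 (15 up and 4 down of 27, adjusted p = 0.0243 but adjusted p = 0.169 with an estimated correlation), P-16 (4 up and 4 down of 27, 5 and 4 adjusted over the list alone, adjusted p = 0.583) and ENZA (5 up and 3 down of 27, adjusted p = 0.468).

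MYC fell with 2-77 (-0.45 ± 0.042), BD98 (-0.96 ± 0.043), P-16 (-0.16 ± 0.042) and ENZA (-0.36 ± 0.042), as with ACBI. MKI67 did not pass with BD98 (-0.04 ± 0.042, adjusted p = 0.46) and fell with P-16 (-0.34 ± 0.042). CDKN1A rose with 2-77 (0.24 ± 0.045) and P-16 (0.21 ± 0.045), fell with BD98 (-0.62 ± 0.046) and did not pass with ENZA (-0.07 ± 0.045, adjusted p = 0.252). TMPRSS2, an androgen-induced protease gene, fell with ACBI (-1.93 ± 0.037), BD98 (-0.38 ± 0.036), P-16 (-1.32 ± 0.037) and ENZA (-2.03 ± 0.038). FKBP5 fell with 2-77 (-0.99 ± 0.044), P-16 (-0.76 ± 0.044) and ENZA (-0.96 ± 0.044). Its fall with BD98 (-0.13 ± 0.043) did not pass without DMSO replicate 1 (-0.10) or with library totals alone (-0.07). CYP1A1 rose with 2-77 (1.04 ± 0.27) and ACBI (1.02 ± 0.27) and did not pass with ENZA (0.40 ± 0.29, adjusted p = 0.297). Its rise with BD98 (0.76 ± 0.28, adjusted p = 0.0252) did not pass without DMSO replicate 1 (0.51), BD98 replicate 2 (0.56) or BD98 replicate 3 (0.77), or in a fit of only the groups compared (0.77).

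**Figure D3:**
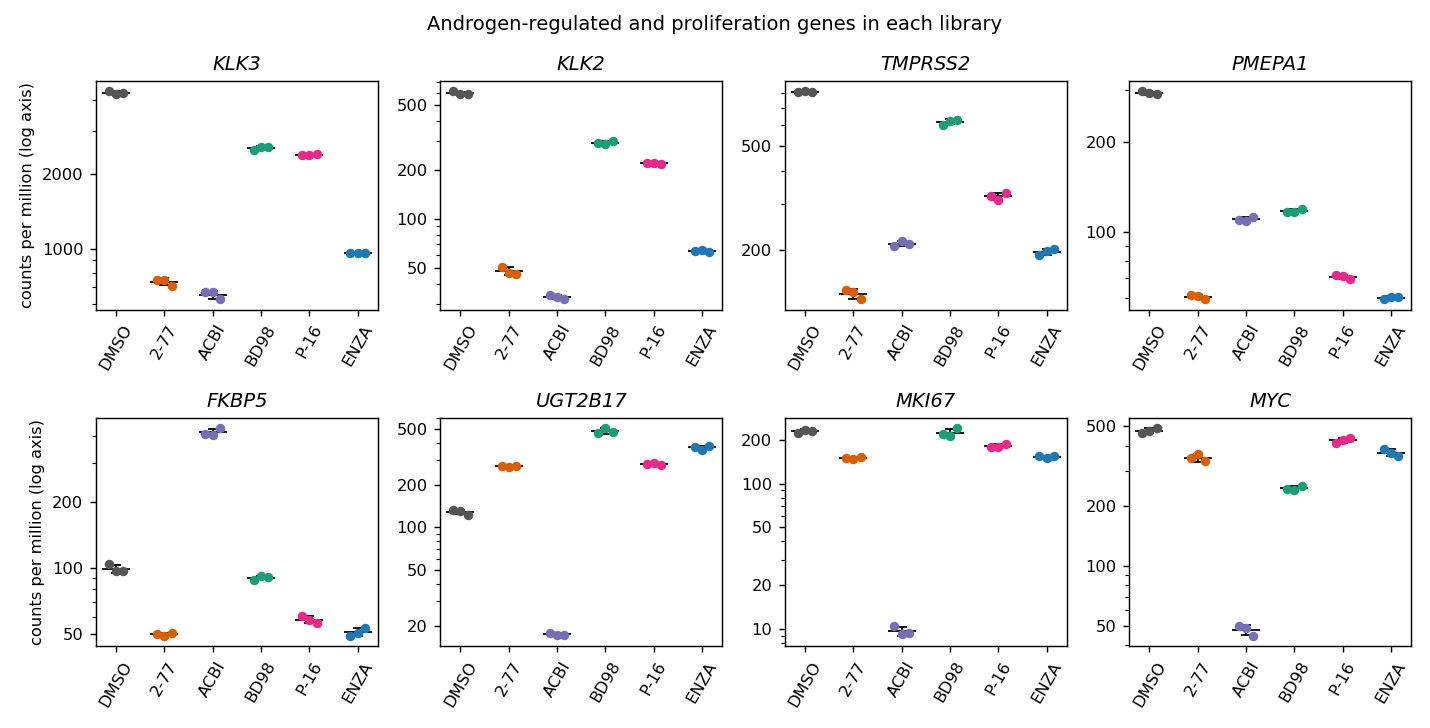
CPM (log axis) of 8 androgen-regulated and proliferation genes in each library, with the mean and SD of the 3 libraries of each condition as bars. KLK3 lies at 4277 CPM in DMSO and at 737, 654, 2557, 2399 and 961.2 CPM with 2-77, ACBI, BD98, P-16 and ENZA, while FKBP5 is higher with ACBI than in DMSO.

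Marker lists of cell types gave 2 calls against DMSO, neither of which held with an estimated correlation. Luminal prostate markers gave 2-77 (3 up and 6 down of 16, 4 and 6 adjusted over the list alone, adjusted p = 0.257), ACBI (7 up and 6 down of 16, adjusted p = 0.711), BD98 (2 up and 10 down of 16, adjusted p = 0.0179 but adjusted p = 0.266 with an estimated correlation), P-16 (3 up and 3 down of 16, adjusted p = 0.789) and ENZA (4 up and 5 down of 16, 4 and 7 adjusted over the list alone, adjusted p = 0.516). SPDEF, an epithelial transcription factor gene, fell with 2-77 (-0.91 ± 0.058), and the keratin gene KRT8 rose (0.24 ± 0.040). Medians and means of this list differed in sign with ACBI (0.03 and -0.51, test up), P-16 (0.01 and -0.08, test down) and ENZA (0.04 and -0.36, test down). Basal epithelial markers gave 2-77 (1 up and 2 down of 7, adjusted p = 0.649), ACBI (2 up and 3 down of 7, adjusted p = 0.634), BD98 (1 up and 5 down of 7, adjusted p = 0.0944), P-16 (2 up and 2 down of 7, adjusted p = 0.697) and ENZA (1 up and 3 down of 7, adjusted p = 0.456), and the integrin gene ITGB4 rose with 2-77 (1.10 ± 0.16) and ENZA (0.90 ± 0.16). Neuroendocrine markers gave 2-77 (3 up and 0 down of 8, adjusted p = 0.112), ACBI (4 up and 2 down of 8, adjusted p = 0.289), BD98 (3 up and 1 down of 8, adjusted p = 0.114), P-16 (2 up and 0 down of 8, adjusted p = 0.0594) and ENZA (1 up and 0 down of 8, adjusted p = 0.442), and the neuronal enolase gene ENO2 rose with 2-77 (1.47 ± 0.051) and P-16 (1.14 ± 0.052). Mesenchymal and stromal markers gave 2-77 (3 up and 4 down of 11, adjusted p = 0.634), ACBI (1 up and 6 down of 11, adjusted p = 0.457), BD98 (1 up and 6 down of 11, adjusted p = 0.0395 but adjusted p = 0.156 with an estimated correlation), P-16 (2 up and 2 down of 11, adjusted p = 0.649) and ENZA (2 up and 3 down of 11, adjusted p = 0.273). Fibronectin (FN1) fell with 2-77 (-0.74 ± 0.034), BD98 (-0.88 ± 0.034) and ENZA (-0.95 ± 0.034) and rose with ACBI (1.44 ± 0.035). With 2-77 the median of this list was 0.03 and the mean -0.22, with the test down. Of the immune cell markers 2 were measured, too few for the list test; 1 fell with each of 2-77, P-16 and ENZA and 1 rose with ACBI. Mitochondrially encoded genes were not analysed here.

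The direct contrast of 2-77 (1 µM) with ENZA (10 µM) asks where 2-77 departs from the antagonist. Androgen-induced genes were slightly lower with 2-77 than with ENZA: KLK3 differed by -0.38 ± 0.031 (adjusted p = 3.77e-10), n = 3 per group. The chemokine receptor gene CXCR4 was 6.41-fold higher with 2-77, at 5.25 ± 0.62 against 0.823 ± 0.149 CPM (2.68 ± 0.21, adjusted p = 2.07e-10), and lies on chromosome 2 from 136114349 to 136118149. Glycolytic and other hypoxia genes were higher with 2-77. Of 15422 genes, 855 (5.5%) differed, 454 higher and 401 lower, with 38 higher and 13 lower by at least 2-fold. Leaving out 1 library gave 499 to 947.

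The other largest differences upward were FOS (1.95 ± 0.18), TMEM74B (1.86 ± 0.22), AKAP12 (1.75 ± 0.10) and PLA2G4D (1.58 ± 0.12), of which FOS is an immediate-early transcription factor gene and AKAP12 a kinase scaffold. The largest downward were DAB1 (-1.31 ± 0.22), MID1 (-1.04 ± 0.10), PCAT1 (-1.03 ± 0.072), GRIK1 (-0.97 ± 0.18) and SLC4A4 (-0.90 ± 0.050), with a highest adjusted p of 0.000706 among these 9. KLK2 and TMPRSS2 were lower (-0.40 ± 0.040 and -0.53 ± 0.037) and CDKN1A was higher (0.31 ± 0.045). No difference passed for FKBP5 (95% interval -0.128 to 0.0557), MKI67 (-0.106 to 0.0673), MYC (-0.172 to -0.000521, adjusted p = 0.293) or BRD7 (-0.0328 to 0.214).

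List tests of the direct contrasts were added after the data were seen. Hypoxia and glycolysis differed between 2-77 and ENZA (16 up and 0 down of 19, 18 and 0 adjusted over the list alone, median 0.39, adjusted p = 2.75e-40). So did androgen-induced genes (1 up and 13 down of 44, 1 and 18 adjusted over the list alone, median -0.09, adjusted p = 7.86e-08), androgen-repressed genes (1 up and 9 down of 15, 2 and 11 adjusted over the list alone, median -0.30, adjusted p = 1.07e-12) and BET-inhibitor-induced genes (5 up and 0 down of 11, median 0.18, adjusted p = 0.00194). DNA replication (1 up and 0 down of 35, 0 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.00348), p53 targets (4 up and 1 down of 24, median 0.06, adjusted p = 0.0208) and neuroendocrine markers (2 up and 0 down of 8, 3 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.0131) passed with few members changed. Calls also came for the integrated stress response (5 up and 2 down of 20, 8 and 5 adjusted over the list alone, median 0.04, adjusted p = 0.0486 but adjusted p = 0.242 with an estimated correlation), the unfolded protein response (0 up and 2 down of 18, 1 and 4 adjusted over the list alone, median -0.06, adjusted p = 0.0243 but adjusted p = 0.0816 with an estimated correlation), heat shock genes (1 up and 0 down of 15, 3 and 0 adjusted over the list alone, median 0.04, adjusted p = 0.0275 but adjusted p = 0.191 with an estimated correlation) and mesenchymal markers (4 up and 0 down of 11, median 0.06, adjusted p = 0.0063 but adjusted p = 0.0752 with an estimated correlation). Mitosis genes (0 up and 0 down of 36, median 0.01, adjusted p = 0.624) and MYC targets (1 up and 0 down of 30, median 0.02, adjusted p = 0.335) did not pass.

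**Figure D4:**
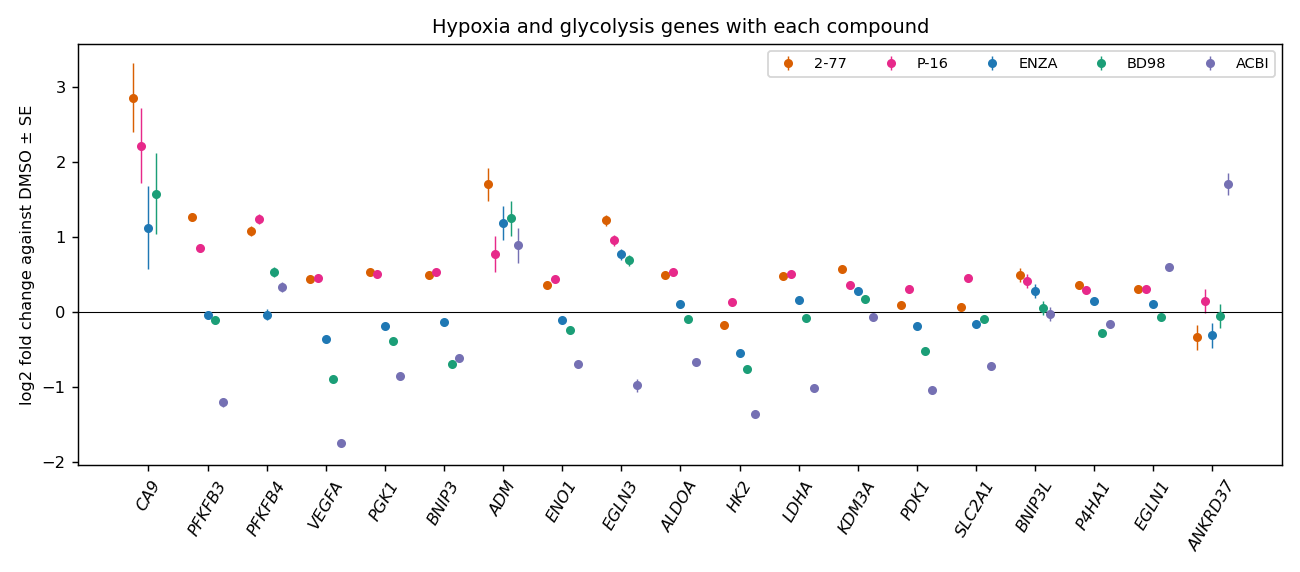
Log2 fold change against DMSO, with SE as bars, of the 19 measured genes of the hypoxia and glycolysis list with each of the 5 compounds; CA9 with ACBI, at 0 counts, is not drawn. With 2-77, 15 of the 19 rose, with P-16 18 rose and with ENZA 8 rose and 7 fell.

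Against P-16 (10 µM), 2-77 (1 µM) gave lower androgen-induced, integrated stress response and unfolded protein response genes. TRPM8 was 11.7-fold lower with 2-77 (-3.55 ± 0.12, adjusted p = 1.69e-19, n = 3 per group) and KLK3 3.25-fold lower (-1.70 ± 0.032, adjusted p = 3.16e-26). CYP1A1 was 8.15-fold lower (-3.03 ± 0.19), and TXNIP, a regulator of thioredoxin and glucose uptake, was 3.04-fold higher (1.60 ± 0.036, adjusted p = 3.05e-24). In all, 3449 genes (22.4%) differed, 1633 higher and 1816 lower with 2-77. Scaled to library totals alone, 3112 differed, 1884 higher and 1228 lower, so that 60.5% instead of 47.3% were higher. At least 2-fold were 53 higher and 101 lower. Further large differences were VWA2 (1.24 ± 0.094) and MAN1A1 (1.18 ± 0.11) upward and GRIN3A (-2.93 ± 0.11), TARP (-2.62 ± 0.13) and ST6GALNAC1 (-2.31 ± 0.16) downward. The pseudogene GUSBP17 also ranked among the 5 largest upward.

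Between 2-77 and P-16 the list test called androgen-induced genes (2 up and 27 down of 44, 3 and 27 adjusted over the list alone, median -0.35, adjusted p = 2.22e-22), the integrated stress response (0 up and 18 down of 20, 0 and 19 adjusted over the list alone, median -0.40, adjusted p = 1.8e-26) and mitosis (0 up and 25 down of 36, 0 and 29 adjusted over the list alone, median -0.22, adjusted p = 3.22e-12). It also called the unfolded protein response (0 up and 12 down of 18, 2 and 14 adjusted over the list alone, median -0.21, adjusted p = 6.88e-09), NRF2 targets (1 up and 11 down of 15, 1 and 12 adjusted over the list alone, median -0.21, adjusted p = 6.67e-08), aryl hydrocarbon receptor targets (0 up and 6 down of 8, 1 and 6 adjusted over the list alone, median -0.41, adjusted p = 4.46e-06) and BET-inhibitor-induced genes (7 up and 0 down of 11, median 0.14, adjusted p = 0.000424). MYC targets (0 up and 12 down of 30, 0 and 14 adjusted over the list alone, median -0.11, adjusted p = 7.26e-06), DNA replication (0 up and 9 down of 35, 0 and 11 adjusted over the list alone, median -0.10, adjusted p = 8.71e-05), fatty acid synthesis (0 up and 7 down of 16, median -0.08, adjusted p = 0.000173) and cholesterol synthesis (1 up and 9 down of 24, 2 and 12 adjusted over the list alone, median -0.11, adjusted p = 0.0222) were called as well. Androgen-repressed genes (8 up and 2 down of 15, median 0.18, adjusted p = 0.0187 but adjusted p = 0.0792 with an estimated correlation), luminal markers (1 up and 5 down of 16, 2 and 7 adjusted over the list alone, median -0.10, adjusted p = 0.00608 but adjusted p = 0.223 with an estimated correlation) and metallothioneins (0 up and 4 down of 5, median -0.51, adjusted p = 0.000589 but adjusted p = 0.0752 with an estimated correlation) depended on the preset correlation. Hypoxia and glycolysis did not pass (4 up and 4 down of 19, 4 and 6 adjusted over the list alone, median -0.02, adjusted p = 0.797). Among single genes MKI67 differed by -0.27 ± 0.042 (adjusted p = 2.11e-05) and MYC by -0.29 ± 0.042 (adjusted p = 7.35e-06).

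Against BD98 (2 µM), integrated stress response genes were higher with 2-77 (1 µM) and androgen-induced genes lower. ACP3 was 9.75-fold higher with 2-77 (3.29 ± 0.050, adjusted p = 7.82e-29, n = 3 per group) and KLK3 3.47-fold lower (-1.80 ± 0.032, adjusted p = 4.66e-27). MKI67 was 1.49-fold lower (-0.57 ± 0.042, adjusted p = 2.68e-12). In this contrast 6474 genes (42.0%) differed, 3192 higher and 3282 lower, with 612 higher and 200 lower by at least 2-fold. With library totals alone 6698 differed, 2551 higher and 4147 lower, 38.1% higher instead of 49.3%. The largest differences were FAM131B (4.03 ± 0.19), SI (3.88 ± 0.21), FOS (3.73 ± 0.23), SEMA6A (3.42 ± 0.067) and ACP3 (3.29 ± 0.050) upward and ALPK2 (-5.04 ± 0.28), PCSEAT (-4.44 ± 0.34), TARP (-4.36 ± 0.11), GRIN3A (-4.29 ± 0.10) and UGT2B28 (-3.54 ± 0.24) downward.

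The lists that parted 2-77 from BD98 were the integrated stress response (19 up and 0 down of 20, median 1.11, adjusted p = 1.66e-25), hypoxia and glycolysis (17 up and 0 down of 19, 18 and 0 adjusted over the list alone, median 0.58, adjusted p = 1.56e-15), DNA replication (0 up and 33 down of 35, median -0.40, adjusted p = 1.58e-16) and mitosis (0 up and 29 down of 36, 0 and 30 adjusted over the list alone, median -0.37, adjusted p = 1.33e-12). Androgen-induced genes (7 up and 31 down of 44, median -0.74, adjusted p = 4.77e-12), interferon response genes (3 up and 19 down of 32, 3 and 20 adjusted over the list alone, median -0.38, adjusted p = 0.000181), NRF2 targets (6 up and 0 down of 15, median 0.12, adjusted p = 0.00363) and heat shock genes (8 up and 0 down of 15, median 0.11, adjusted p = 0.00632 but adjusted p = 0.103 with an estimated correlation) were called too. The unfolded protein response did not pass (6 up and 1 down of 18, median 0.02, adjusted p = 0.129).

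Against ACBI (0.2 µM), proliferation genes were higher with 2-77 (1 µM). MKI67 was 15.5-fold higher (3.96 ± 0.055, adjusted p = 1.59e-30, n = 3 per group) and MYC 7.26-fold higher (2.86 ± 0.046, adjusted p = 4.54e-29), whereas HES6 was 54.8-fold lower (-5.78 ± 0.058, adjusted p = 2.79e-30) and FKBP5 8.33-fold lower (-3.06 ± 0.044). KLK3 differed by 0.17 ± 0.031 (adjusted p = 1.65e-05). Of the genes tested, 10823 (70.2%) differed, 5673 higher and 5150 lower, with 1982 higher and 1021 lower by at least 2-fold. Among the largest differences upward with fitted values were IL1RN (8.01 ± 0.16) and DIO3 (7.80 ± 0.12), where IL1RN is the antagonist of the interleukin-1 receptor. MRGPRE had 1 count over the 3 ACBI libraries against 438, a ratio of 406 (95% counting interval 72.5 to 1.61e+04). GLP1R had 1 against 366, a ratio of 339 (60.5 to 1.34e+04). Downward they were LAT2 (-6.64 ± 0.15), HES6 (-5.78 ± 0.058), HPGD (-5.50 ± 0.18), GALNT12 (-5.34 ± 0.28) and CHRM4 (-5.08 ± 0.29).

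All 35 DNA replication genes (35 up and 0 down of 35, median 2.23, adjusted p = 5.67e-18) and all 30 MYC targets (30 up and 0 down of 30, median 0.88, adjusted p = 4.69e-13) were higher with 2-77 than with ACBI, as were mitosis genes (35 up and 0 down of 36, median 3.45, adjusted p = 1.92e-18), the integrated stress response (18 up and 0 down of 20, median 1.12, adjusted p = 2.98e-10) and hypoxia and glycolysis (17 up and 2 down of 19, median 1.10, adjusted p = 1.87e-07). Androgen-induced genes (5 up and 35 down of 44, median -1.43, adjusted p = 2.77e-13), BET-inhibitor-induced genes (1 up and 10 down of 11, median -1.11, adjusted p = 5.59e-05) and cholesterol synthesis (0 up and 18 down of 24, median -0.54, adjusted p = 4.63e-06) were lower. Androgen-repressed genes were called (9 up and 2 down of 15, median 1.09, adjusted p = 0.00168). The unfolded protein response (11 up and 5 down of 18, median 0.40, adjusted p = 0.0267 but adjusted p = 0.0845 with an estimated correlation), NRF2 targets (9 up and 2 down of 15, median 0.37, adjusted p = 0.0444 but adjusted p = 0.0755 with an estimated correlation) and heat shock genes (12 up and 2 down of 15, median 0.47, adjusted p = 0.00458 but adjusted p = 0.092 with an estimated correlation) lost their calls with an estimated correlation. Ribosomal RNA took 8.6% of ACBI replicate 3 in these contrasts as well.

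The changes against DMSO were also compared gene by gene between compounds. Across genes, which are not independent replicates, the log2 fold changes of 2-77 and ENZA had a Pearson r of 0.875. The same genes rose with both in 2276 cases, fell with both in 2302 and were called in opposite directions in 25, where independent calls would give 578, 562 and 1139. In 5 simulations with the same DMSO libraries for both groups and the changes of ENZA dealt to genes at random, at most 481 rose and 479 fell with both and at least 818 went apart. Both contrasts use the same 3 DMSO libraries, and unchanged groups simulated against them gave a mean r of 0.545, at a mean covariance of 0.0199 against 0.1969 here. The correlation was 0.777 for 2-77 and P-16 and 0.74 for P-16 and ENZA, where simulated unchanged groups gave means of 0.53 and 0.525. For BD98 and ENZA (0.513), 2-77 and BD98 (0.497) and BD98 and P-16 (0.438) it lay below the simulated means of 0.518, 0.517 and 0.514. The same held for the pairs of ACBI with 2-77, BD98, P-16 and ENZA, at 0.311, 0.316, 0.187 and 0.321 against 0.54, 0.527, 0.525 and 0.535. Covariances in these 7 pairs ran from 0.0702 (ACBI and P-16) to 0.1665 (ACBI and BD98), and those of simulated groups reached at most 0.0212. Of the genes called with both, 99.5% went the same way for 2-77 and ENZA (50.7% to 53.6% in those simulations) and 72.6% for 2-77 and ACBI (49.5% to 50.5% in the like ones). The 3 DMSO libraries were too few to give each contrast its own controls.

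**Figure D5:**
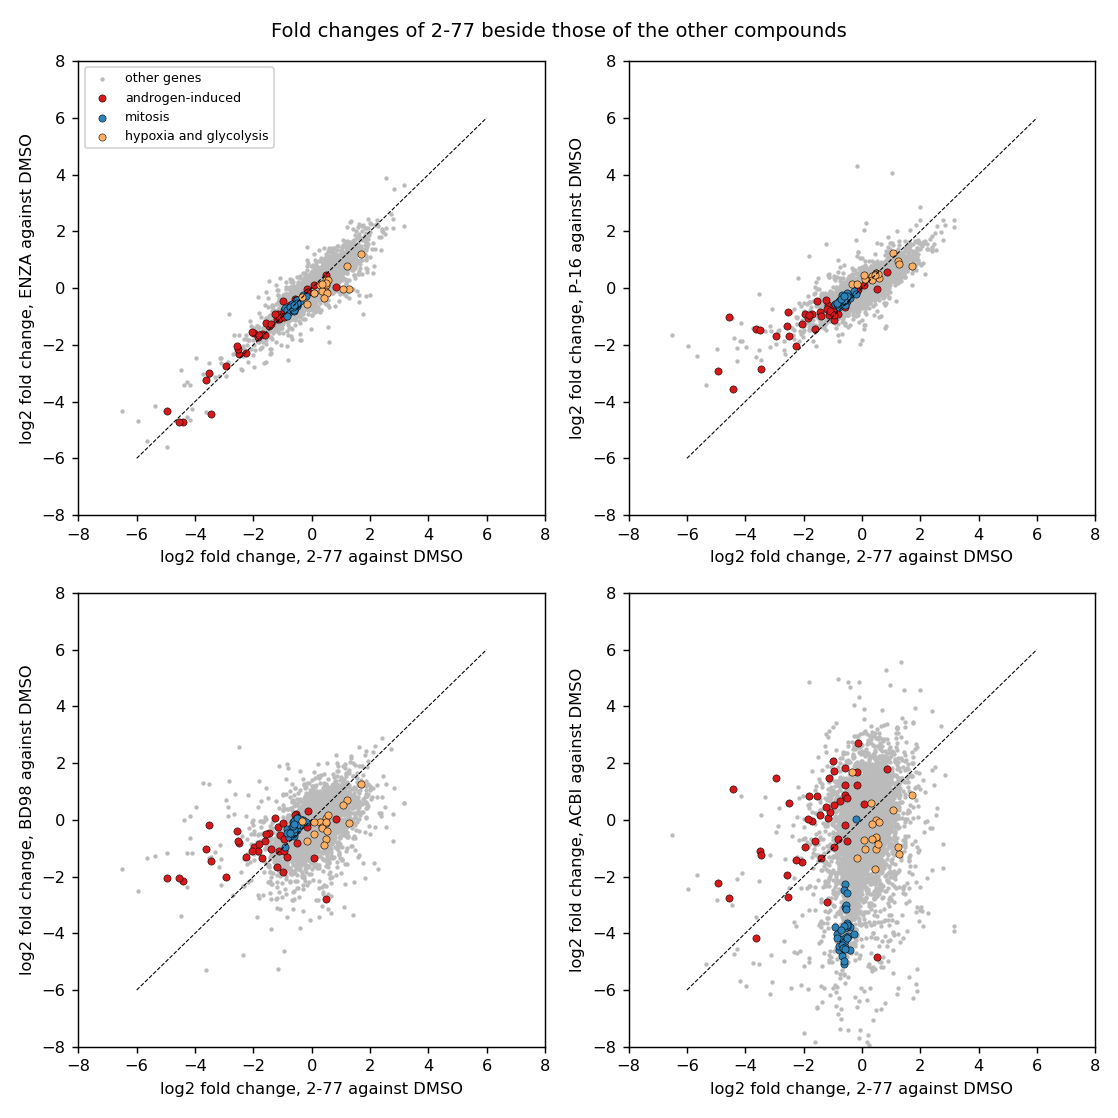
Log2 fold change against DMSO with 2-77 (x axis) and with each other compound (y axis), one point per gene for 14154 genes with at least 1 CPM in a group and counts in all 6, with 2 genes outside the axes. The spread along the diagonal is narrowest for ENZA, where r is 0.875 over all genes tested.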

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

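Fits without ribosomal RNA genes, lists without ACBI replicate 3 and list tests of the direct contrasts were chosen only after the data were seen, and the other alternatives before. The numbers of changed genes stayed within 1.5 times the reported ones under every alternative, except in the contrast of 2-77 with ENZA when 1 library was left out. There, leaving out each library in turn gave 499 to 947 genes against 855, with 499 without 2-77 replicate 1, 560 without 2-77 replicate 2, 555 without ENZA replicate 1 and 947 without 2-77 replicate 3; the cause was not tested. With a replicate block in the model, 6107, 10997, 7388, 3547 and 5466 genes changed with 2-77, ACBI, BD98, P-16 and ENZA, and 10758, 6318, 3250 and 758 differed between 2-77 and ACBI, BD98, P-16 and ENZA. Among genes with a mean log2 CPM of at least 4 (9034 genes), the correlation of fold changes was 0.558 for 2-77 and BD98, 0.822 for 2-77 and P-16, 0.923 for 2-77 and ENZA, 0.272 for ACBI and BD98, 0.526 for BD98 and ENZA and 0.779 for P-16 and ENZA; the cause was not tested.

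Of 693 named-gene results, 85 gene and setting pairs lost their call and 18 gained one, 68 of the losses on leaving out 1 library. No named-gene call was reversed. The fry test, which asks whether a list moves one way on balance without comparing it with other genes, pointed down for androgen-induced genes with ACBI (adjusted p = 1.53e-05), where camera pointed up without a call, and the cause was not tested. It added 48 list calls. An estimated correlation ended 9 of 56 list calls. A replicate block ended those of androgen-repressed genes with ACBI (adjusted p = 0.053) and of hypoxia genes with BD98 (0.0552). Library totals alone ended those of luminal markers (0.0576) and hypoxia genes (0.0841) with BD98, and added basal markers with BD98 (0.0489) and neuroendocrine markers with P-16 (0.0487). The smallest simulated folds were recovered in 66% of genes. With 191 calls there and 6280 for 2-77 against DMSO, that share need not carry over.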

Other observations

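The tests of shared DMSO libraries, of a mixture in 1 library, of GC content, length and depth for P-16 against ENZA, of one factor for RNA content and of other splits of the libraries were chosen only after the results were seen. Glucocorticoid-induced genes that stand on neither androgen list moved both ways with ACBI. The list of these genes was written before it was tested, and 20 of its 24 members were measured, of which 9 rose and 9 fell, at a median log2 fold change of 0.01. ZFP36, which destabilizes inflammatory messenger RNAs, rose (1.18 ± 0.081), as did the transcription factor gene KLF9 (0.83 ± 0.044) and the amine oxidase gene MAOA (0.73 ± 0.035). BCL6, a transcriptional repressor, fell (-1.92 ± 0.056), as did KLF15 (-1.16 ± 0.055) and the calcium-binding protein gene S100P (-4.64 ± 0.15). The glucocorticoid receptor gene NR3C1 rose from 2.01 to 7.69 CPM (log2 fold change 1.93, edgeR adjusted p = 1.34e-07).

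The changes with 2-77 and with ENZA ran together across genes. Their covariance was 0.1969 against at most 0.0225 for simulated unchanged groups that share the same 3 DMSO libraries, which argues against shared controls as the whole cause, although they may add a part. Mislabelled libraries are argued against by placement: 0 of the 6 libraries lay nearer to the other group on genes called without it, and 2-77 replicate 3 came closest (0.441 from ENZA and 0.195 from its own group). Without any 1 of the 6 the correlation was at least 0.848, which argues against a mixture in 1 library, whereas a mixture in several was not tested and stays open. Without the 160 genes of the androgen, mitosis, DNA replication and MYC lists r was 0.868, which decides nothing, as 15262 genes remained. Lowered androgen signalling with both compounds was not tested apart from other effects and stays open.

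Hypoxia and glycolysis genes were higher with 2-77 than with ENZA (median 0.39) and with P-16 than with ENZA (median 0.50, with 14 of 19 members higher and 0 lower by edgeR). Removal of the trend on GC content and transcript length left a median of 0.388 for 2-77 against ENZA and 0.511 for P-16 against ENZA. These values argue against that trend as the whole cause. Thinning of every library to 16835093 counts left 0.396 and 0.511. Thinning keeps the expected share of each gene, so it could hardly move these medians and does not decide on depth. Differences in cell density or medium at harvest, which the labels do not give, and an effect of the compounds on glycolysis were not tested and stay open.

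Androgen-induced genes moved both ways with ACBI. Ribosomal RNA in ACBI replicate 3 is argued against as the cause, since 34 members, 17 up and 17 down, still differed by at least 1.5-fold without that library. One common factor for the RNA content of the cells would shift all members alike and so cannot by itself give members that rose and members that fell. The interquartile range of their log2 fold changes, 2.13, restates that spread and is no separate test. A gain of glucocorticoid receptor activity might raise the members that rose, and the median of glucocorticoid-induced genes outside the androgen lists was 0.009 (bootstrap interval -0.488 to 0.654), a value over members that went both ways, which decides nothing. That explanation stays open.

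For each of the 9 contrasts the 6 libraries can be split into groups of 3 in 10 ways, and 1 of the 10, the real one, gave as many genes, but 10 splits cannot give a share under 0.05. Fitted to the 6 libraries alone with edgeR, the real split called 6309 genes (2-77 vs DMSO), 10418 genes (ACBI vs DMSO), 7678 genes (BD98 vs DMSO), 4531 genes (P-16 vs DMSO), 6380 genes (ENZA vs DMSO), 10122 genes (2-77 vs ACBI), 6255 genes (2-77 vs BD98), 3729 genes (2-77 vs P-16) and 1050 (2-77 vs ENZA). The highest count of any other split was 8 for 2-77 vs ENZA, 1 for P-16 vs DMSO and 0 for the other 7 contrasts.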
